A study of Mus musculus with 15 samples.

How the data were processed

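DNA from 15 tumours of female mice homozygous for the Mcm4 Chaos3 mutation was measured on 2-colour comparative genomic hybridisation arrays, 1 array per tumour. Per the labels, Cy5 held the tumour DNA and Cy3 a reference of wild-type C57BL/6J and C3HeB/FeJ DNA. The labels also give a number of copy-number variants per tumour; how it was made is not given in the sources used here. Each array holds 974016 spots, of which 6755 are controls. Per the file headers, the deposited intensity values were made by Feature Extraction 10.7.3.1, with background subtraction and spatial detrending, multiplicative detrending and linear dye normalization. The deposited log10 ratios equal the log10 of red over green processed signals to within 0.001 except at 631 or fewer spots per array, where they differ by at most 0.28, and the deposited series table holds the same log10 values. The deposited signals also come with the software's flags for outlier spots, saturated spots and spots well above background. Median raw signals per array ranged from 99 to 283 in red and from 117 to 234 in green.

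Ratios were computed as log2 of the green over the red processed signal. Control spots and spots flagged as outliers were left out (at most 0.0463% of spots on an array), spots of 1 probe were averaged, and each array was centred on its autosomal median. The design had red over green, the orientation of the labels; the sign was turned after the data were seen, because the green channel carried the changes. No dye swap was made. The labelled orientation was kept as an alternative.

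Probe positions are those of the array design. The gene table used here is of assembly GRCm38.p6, and probes lie beyond its last gene on chromosome 1 (517 probes), chromosome 5 (280), chromosome 7 (3687) and chromosome 8 (903), so the positions are of another build, which is not given in the sources used here. The files used hold no gene names. The planned gene values were therefore replaced by medians of 100 kb bins with at least 3 probes, 24793 bins, of which 23357 are autosomal. The table served only for the chromosome of a named gene. The 9 gene lists and the antigen receptor loci could not be placed, and their rotation test was not run. A correction for GC content needs the probes' sequences in a genome, which were not used here.

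Each chromosome was segmented by penalised least squares, with a penalty of 10 times the noise variance times the log of the number of probes. Values were limited to 3 noise SDs around a running median of 11 probes. A called segment had at least 10 probes and a mean of 0.25 or more in size; neighbouring segments past that size in 1 direction were joined into 1 call. Counts and altered shares cover the 19 autosomes. Recurrence counted calls of at least 100 kb per bin, and its p-value came from 10000 rotations of each tumour's calls around the autosomes.

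Tumours were grouped by the labels into 12 mammary and 3 non-mammary, and mammary tumours into 5 from crosses (2 F1, 3 F2) and 7 congenic. Single values were compared by two-sided exact permutation tests and counts of tumours by Fisher's exact test. Correlations had permutation p-values, exact within backgrounds and from 100000 resamples over all tumours. Bins were tested with limma (lmFit, eBayes) at a Benjamini-Hochberg adjusted p of 0.05, and for mammary tumours against the reference also a mean of 0.2 or more in size. The reference stood in the other channel of each array, so that test leaves out the reference's own spread. Mammary against non-mammary had background as a covariate. Groups, covariates, the call thresholds, the list of alternatives, the rule for named items and the tests of segments, altered shares, label numbers, recurrence and limma were chosen before the data were examined. The penalty value, the bin size, the turned sign and the tests of ratios and calls in single regions and stretches were not.

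The rule named Nf1, Mcm4, Trp53 and Myc, the 5 regions per direction called in the most mammary tumours with peaks at least 5 Mb apart, and up to 8 bins per direction past the threshold of each limma comparison with at least 5 probes, or the 3 of smallest p where fewer passed; the text gives some of these in full. Named positions replace genes in it, and list members on whole-chromosome changes were named after those changes were seen. Inner segments of losses, high-ratio calls and the second loss on chromosome 11 were chosen after their values were seen.

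Alternatives covered normexp background correction (offset 50, on median signals), the series table, centring on the mode, probes well above background, size thresholds of 0.15 and 0.35, probe minimums, the penalty, segment lengths, bin summaries, limma settings, slide lot, a replicate block and leaving out each tumour. Chosen after seeing the data were the labelled dyes, removal of a probe trend shared by arrays, scan day, single slide lots for the crosses, single backgrounds, strain loci, the halved penalty, the numbered tumours without a block and leaving out tumours for whole stretches.

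Segmentation was tested on simulated data: at a size of 1, it found 100% of segments of 50 probes and 58.4% of those of 20 probes. At a size of 0.4 it found 87.4% of segments of 200 probes (39.5% on the array with the lowest share) and 1.40% of those of 50 probes. It made 0 false calls in 15 arrays. The simulated noise was each array's deviations from a running median, drawn at random over the genome. Waves along the genome and probe trends shared by arrays were thereby removed, so the 0 does not cover false calls that these may cause. The limma step was tested on simulated data with 200 changed bins; at a size of 0.5 it found 100% against the reference, 97.5% for mammary against non-mammary, 100% for cross against congenic and 90.5% for F1 against F2. At a size of 0.2 it found 99%, 58%, 61% and 6% of the bins in these comparisons. The simulated values were independent and normal, with each bin's median absolute deviation over the mammary tumours as spread. Every tumour of a group was shifted alike. Changes of unlike size, or in only some tumours, widen the spread, so these shares do not tell how many such changes limma would find.

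Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.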

Results

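DNA copy number was measured on arrays in 15 primary tumours that arose spontaneously in female mice homozygous for the Chaos3 point mutation of Mcm4. Mcm4 encodes a subunit of the helicase that unwinds DNA at replication forks. Per the labels, 12 tumours were mammary and 3 were not. The mammary tumours comprised 2 from C3HxB6 F1 mice, 3 from C3HxB6 F2 mice and 7 from C3H congenic mice, of which 1 carries no number. The others were a uterine tumour of a congenic mouse (congenic 7), a uterine tumour of an F2 mouse (F2 4) and a bone tumour of an F2 mouse (F2 5). Each tumour was hybridised once, beside wild-type reference DNA from C57BL/6J and C3HeB/FeJ mice, to a 2-colour array of 963261 distinct probes. Autosomal probes had a median spacing of 1782 bp, and 95.1% to 99.1% of spots per array were well above background. The noise between neighbouring probes ranged from 0.21 to 0.40 on the log2 scale. The 5 cross mammary tumours were scanned on days 1 and 2, and the other 10 tumours on days 3 and 4. Among mammary tumours, background and scan day therefore cannot be told apart. One array per tumour and 3 non-mammary tumours limit the precision, and the p-values measure only the spread between these tumours.

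Ratios are given as log2 of Cy3 over Cy5, so that a negative value is a loss, because the Cy3 signal carried the changes. The labels assign the tumour to Cy5 and the reference to Cy3; with the labelled dyes every loss below is a gain and every gain a loss. In the 108 called segments of at least 1 Mb, Cy3 deviated from the other 14 arrays by a median size of 0.46, and Cy5 by 0.01. The Cy3 deviation was the larger in 106 of the 108 segments, and the Cy3 share of the change had a median of 1.01 in processed and 1.02 in raw signals. No array had its dyes swapped, so a dye bias would not cancel. Array positions lie beyond the last GRCm38 gene on several chromosomes, by as many as 3687 probes on chromosome 7, and the build is not given in the sources used here. Focal regions are therefore given by array position and are not named by genes.

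**Figure D1:**
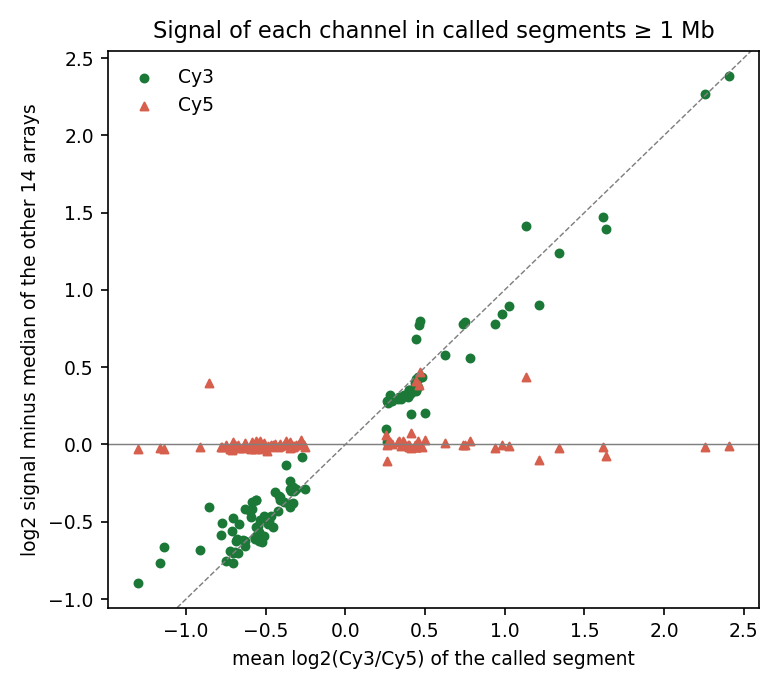
Mean log2(Cy3/Cy5) of each called segment of at least 1 Mb (x axis, 108 segments) against the log2 signal of each channel minus its median over the other 14 arrays (y axis). Most circles (Cy3) lie near the dashed line of equal change, whereas most triangles (Cy5) lie near 0, with a median size of 0.01. The Cy3 deviation was the larger in 106 of the 108 segments.

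Mammary tumours carried more called segments than the non-mammary tumours, 31.7 ± 12.6 (SD, n = 12) against 11.7 ± 9.07 (SD, n = 3). Losses outnumbered gains in the mammary tumours, 24.9 ± 8.11 against 6.75 ± 5.96 per tumour, whereas the non-mammary tumours had 3.67 ± 3.06 losses and 8 ± 6.25 gains (SD, n = 12 and n = 3). The altered share of the autosomes ranged from 0.339% in congenic 1 to 19.1% in F2 3 among mammary tumours, with a mean of 6.80% ± 6.58. It was 0.207% ± 0.0870 in the non-mammary tumours (SD, n = 3). Uterine congenic 7 had 2 called segments, uterine F2 4 had 20 and bone F2 5 had 13. Probe noise, which raises the penalty and lowers detection, was highest in bone F2 5 (0.40) and uterine congenic 7 (0.38). It was lowest in uterine F2 4 (0.21) and ranged from 0.22 to 0.37 in mammary tumours, where F2 2, at 0.37, had 38 segments. How much noise adds to the difference in counts was not tested. At loci where the Cy5 signal differed between scan days, or at chromosome 4 from 21100001, lay 11 of the 20 segments of F2 4, 8 of the 13 of F2 5 and 1 of the 2 of congenic 7. Without such segments, the non-mammary mean fell to 5 ± 4 (SD, n = 3), with 2.67 ± 3.06 losses and 2.33 ± 1.15 gains, and the mammary mean to 29 ± 10.5 (SD, n = 12), with 23.8 ± 7.85 losses and 5.25 ± 4.79 gains. The difference was then 24 (exact permutation p = 0.0022, the smallest possible). The difference of 20 segments passed a two-sided exact permutation test (p = 0.0198, Benjamini-Hochberg value 0.0396 over 4 tests). It passed within background as well (exact permutation p = 0.0238). The difference was 27.9 in slide lot B (5 against 3 tumours, exact permutation p = 0.0714), 14.3 on scan day 4 (2 against 3, exact permutation p = 0.3, smallest possible 0.1) and 12.9 on days 3 and 4 (7 against 3, exact permutation p = 0.0333). The altered share differed by 6.59 percentage points (exact permutation p = 0.0637, Benjamini-Hochberg value 0.0850), which did not pass. Within batches it differed by 10.6 points in lot B (exact permutation p = 0.0179), 11.2 on day 4 (exact permutation p = 0.1) and 4.03 on days 3 and 4 (exact permutation p = 0.075). The segment call ended without uterine congenic 7 (difference 15.2, exact permutation p = 0.143), without bone F2 5 (20.7, exact permutation p = 0.0549) and at a size threshold of 0.35 (17.8, exact permutation p = 0.0593). Counting only segments of at least 1 Mb gave a difference of 6.5 (exact permutation p = 0.0725).

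**Figure D2:**
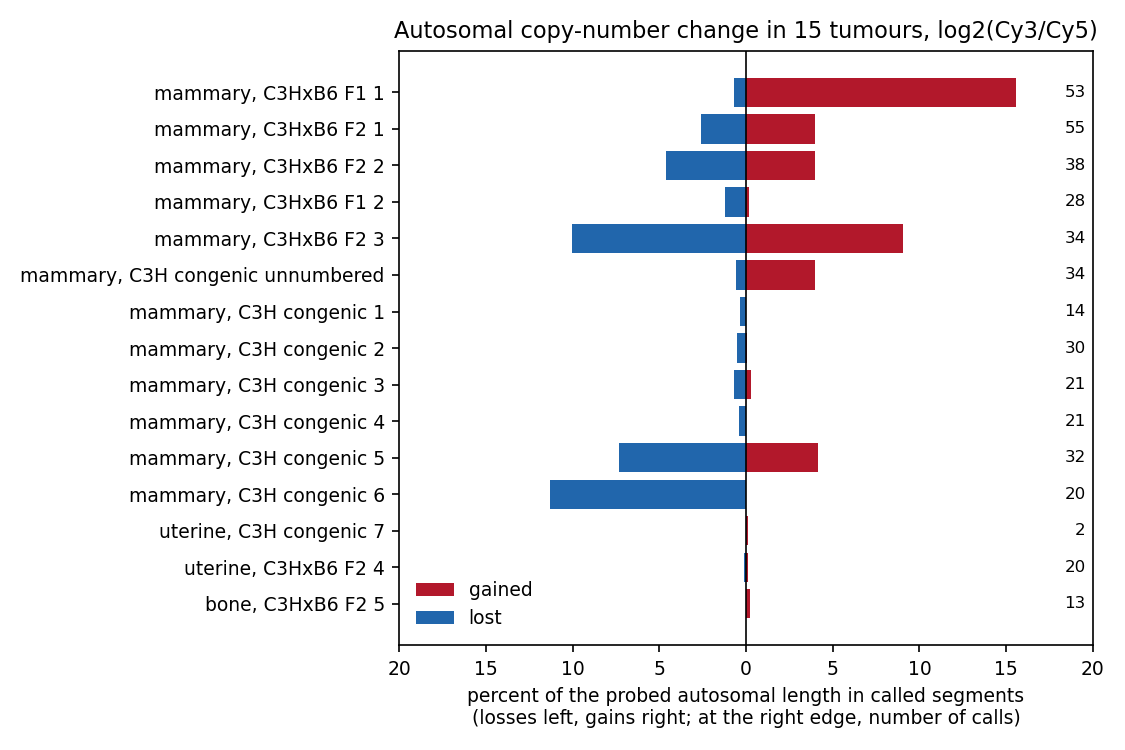
Percent of the probed autosomal length in called losses (blue, left) and called gains (red, right) in each of the 15 tumours, with the number of called segments at the right edge. Mammary tumours span 0.339% to 19.1% altered, and the 3 non-mammary tumours lie between 0.113% and 0.285%.

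Whole chromosomes, taken as changes over at least 80% of the probed length, were altered in 6 of the 12 mammary tumours and in none of the 3 non-mammary tumours. Chromosome 1 was gained in F1 1 and F2 3, at chromosome medians of 0.40 and 0.42. It carries 11 genes of the lists, among them the replication helicase genes Mcm3 and Mcm6 and the p53 inhibitor gene Mdm4. Chromosome 2, which holds 18 listed genes including Notch1 and Aurka, was gained in F1 1 at 0.42. Chromosome 18, with the tumour suppressor genes Apc and Smad4, was gained in F2 2 at 0.77. Chromosome 16, which holds Mcm4 itself, was gained in the unnumbered congenic tumour at 0.28. Losses took chromosome 12, with Akt1 and the mammary luminal gene Foxa1, in congenic 5 at -0.38 and congenic 6 at -0.34. Congenic 6 also lost chromosome 7 at -0.32, with 15 listed genes including Hras, Ccnd1 and the DNA repair genes Blm and Palb2. F2 3 lost 80.1% of chromosome 14, which carries the tumour suppressor genes Rb1 and Bap1, at a chromosome median of -0.39. F2 2 lost chromosome X at -0.32. The oncogene Myc lies on chromosome 15, whose median stayed between -0.05 and 0.09 in the 12 mammary tumours. Nf1, which encodes a negative regulator of Ras, and the tumour suppressor gene Trp53 lie on chromosome 11, whose median ranged from -0.21 to 0.05. A chromosome median cannot show a focal loss, and chromosome 11 held such losses, given below. Whether Nf1 or Trp53 lies in one of them is not known here. Genes were placed by chromosome alone, so it is not known whether Rb1 or Bap1 lies in the lost part of chromosome 14. These single-tumour values have no replicate check, and they turn sign with the labelled dyes.

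Losses recurred at the same positions in the mammary tumours. A called loss of at least 100 kb covered the same 100 kb bin in 6 or more of the 12 mammary tumours in 51 autosomal bins, which formed 6 stretches on chromosomes 4, 5, 11 and 12. The most frequent, at chromosome 11 from 79100001 to 79300000, was lost in 11 of 12. Rotating each tumour's calls around the autosomes gave a highest count at least as large with a permutation p of 0.0001, the smallest that 10000 rotations allow. No bin was gained in 6 or more tumours. The highest count was 4 of 12 (rotation permutation p = 0.111). The result for gains held in 12 of 15 alternatives and that for losses in 13 of 15, and the exceptions are given below by setting.

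**Figure D3:**
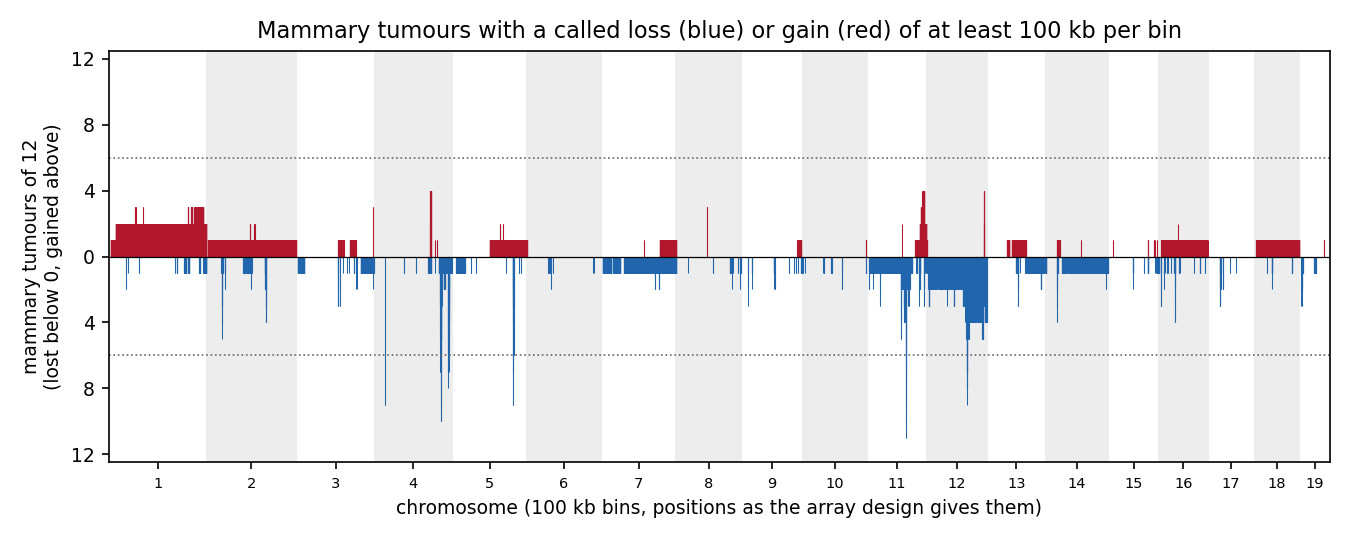
Number of the 12 mammary tumours with a called loss (blue, below 0) or gain (red, above 0) of at least 100 kb in each 100 kb bin of the autosomes, in array order; dotted lines mark 6 tumours. The tallest loss, on chromosome 11, reaches 11 tumours, and no gain exceeds 4.

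On chromosome 11, a called loss overlapped the stretch from 78600001 to 79500000 in 12 of 12 mammary tumours and in 0 of 3 non-mammary tumours. In all 12 the loss had steps, with a deep inner segment beside a shallower one. The deepest segment per tumour averaged -1.96 ± 0.49 (SD, n = 12), was between 0.0607 and 0.504 Mb long, and lay 1 or more below 0 in 11 tumours. It reached -2.69 from 79050985 to 79415797 in F1 1. In F2 3 a segment at -1.80 from 78852316 to 79356444 lay within a loss from 4701913 to 84859219 at a mean of -0.42. The inner segments did not share 1 interval: that of congenic 6 (-0.96) ended at 79156459, and that of congenic 4 (-2.04) began at 79316312. At the peak the log2 ratio was -1.31 ± 0.74 in mammary tumours (SD, n = 12) and -0.02 ± 0.01 in the others (SD, n = 3). The overlap counts differed by Fisher's exact test (two-sided p = 0.0022, Benjamini-Hochberg value 0.0132 over 6 stretches). The ratios at the peak differed by -1.29 (two-sided exact permutation p = 0.011), which did not pass over the 10 regions named (Benjamini-Hochberg value 0.0513). Taken as each tumour's median over the bins of the whole stretch, they differed by -0.76 (exact permutation p = 0.0615), which did not pass. Such a median barely registers a loss over a small part of the stretch. Congenic 4, with a call of 0.20 Mb at -1.36, stood at -0.03. With normexp correction 11 of 12 kept a call. The difference over the whole stretch was then -0.33 (exact permutation p = 0.0198), and the mammary mean moved from -0.76 to -0.35. On scan day 4, both mammary tumours and none of the 3 others had the loss. The stretches were chosen on mammary calls, so these tests are not independent of that choice, and with the labelled dyes the region is a gain.

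**Figure D4:**
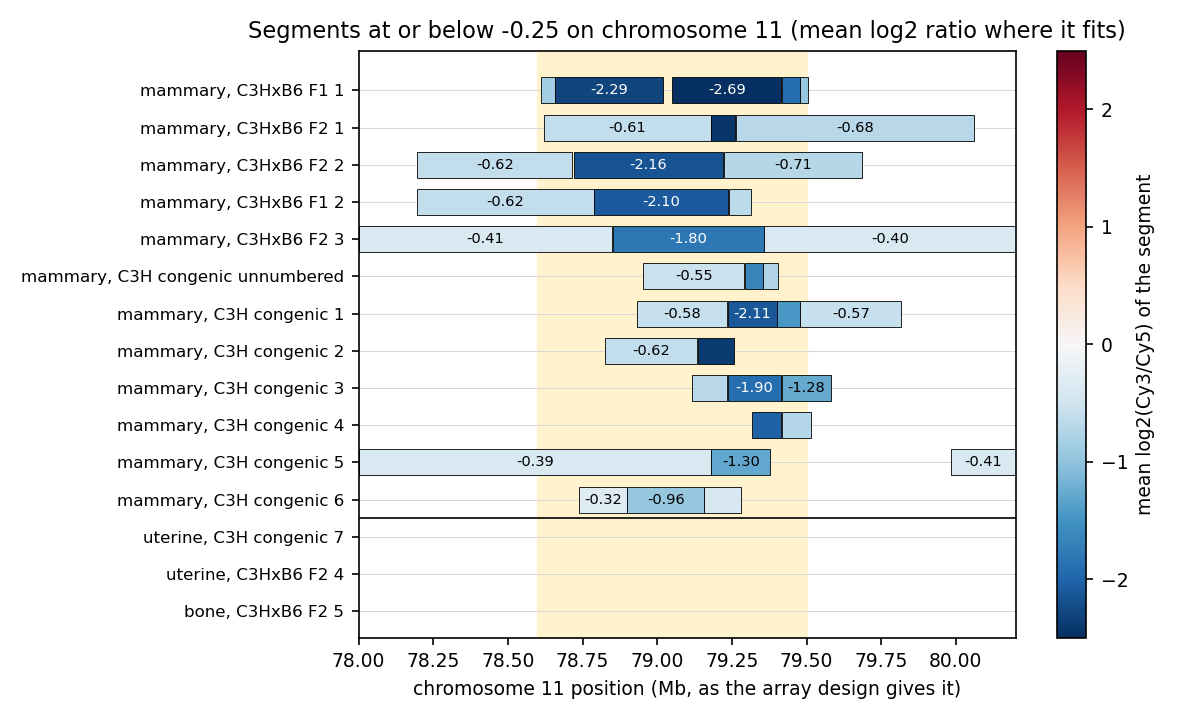
Segments with a mean log2(Cy3/Cy5) of -0.25 or below on chromosome 11 in each of the 15 tumours (x axis, position in Mb), coloured by their mean, with the stretch lost in 6 or more mammary tumours shaded. The 12 mammary tumours each hold a loss in steps, deepest at -2.69 in F1 1, and the 3 non-mammary tumours hold none.

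Of the other 5 recurrent stretches, 4 were lost in mammary tumours and in none of the 3 non-mammary tumours. Here too a stretch counts as lost in a tumour where a call overlaps any part of it. These stretches too were chosen on mammary calls, and the non-mammary tumours had few losses anywhere (0.0510% of the autosomes, against 3.36% in mammary tumours). A count of 0 of 3 is therefore likely at most such stretches, and the Fisher tests below say little about any single one. At a single bin the highest counts were 10 for chromosome 4 from 132600001, 9 for chromosomes 5 and 12, and 8 for chromosome 4 from 148400001. Chromosome 4 from 132600001 to 133700000 was lost in 11 of 12, with a deepest segment averaging -0.56 ± 0.30 (SD, n = 11; Fisher's exact p = 0.00879, Benjamini-Hochberg value 0.0264), and in 9 of 12 with normexp correction. That segment stood at only -0.28, -0.27 and -0.28 in congenic 3, congenic 4 and congenic 6, close to the size threshold of 0.25, so the count depends on that threshold. Chromosome 5 from 124300001 to 125300000 was lost in 10 of 12 at -0.94 ± 0.59 (SD, n = 10), and chromosome 12 from 80700001 to 81800000 in 10 of 12 at -0.58 ± 0.13 (SD, n = 10; for both, Fisher's exact p = 0.022, Benjamini-Hochberg value 0.0330). The chromosome 12 loss was not focal in 4 of its 10 tumours: it spanned 41.9 Mb in F2 2, 37.2 Mb in F2 3 and nearly the whole chromosome in congenic 5 and congenic 6. Both losses on chromosome 4 in congenic 5 were a single loss of 26.1 Mb. Chromosome 4 from 148400001 to 149200000 was lost in 9 of 12 at -1.40 ± 0.70 (SD, n = 9; Fisher's exact p = 0.0440), which did not pass after adjustment (0.0527). Segments 1 or more below 0 occurred there in 6 tumours, on chromosome 5 in 3, at chromosome 4 from 132600001 in 1 and on chromosome 12 in 0. The 2 congenic mammary tumours of scan day 4 both had the losses on chromosome 12 and at chromosome 4 from 132600001, and 1 of them each of the others. The sixth stretch, chromosome 4 from 21100001 to 21300000, was lost in 9 of 12 mammary and in 3 of 3 non-mammary tumours (Fisher's exact p = 1). Its log2 ratio averaged -1.89 ± 1.06 (SD, n = 12) and -2.67 ± 0.30 (SD, n = 3). Every congenic tumour, uterine congenic 7 included, stood between -3.02 and -2.31. F1 1 and F1 2 stood at -0.75 and -0.73, although only F1 1 had a call. F2 tumours stood at 0.05, -0.53 (F2 3, no call), -2.77, -2.47 and -2.52. All 10 tumours of scan days 3 and 4, F2 4 and F2 5 included, thus stood between -3.02 and -2.31, and of those of days 1 and 2 only F2 2 did. The values followed scan day more closely than background or tissue, and whether this loss arose in the tumours was not tested. Without dim probes, those near background, 2 of 12 mammary and 0 of 3 non-mammary tumours kept a call, and the mammary mean was -0.56. Probes were left out per array, and a deep loss itself dims Cy3, so this setting can remove the lost probes. The log2 Cy3 signal here was -3.33 to -2.8 in the congenic tumours, whereas Cy5 was -0.23 to 0.11 on all arrays. The setting therefore cannot tell whether the loss is an effect of dim probes. With normexp background correction, whose offset draws ratios of dim signals towards 0, the mammary mean was -0.67. As medians over whole stretches, the log2 ratios of mammary and non-mammary tumours did not differ past 0.05 at any of these 5 (exact permutation p from 0.0505 to 0.255). Some passed 0.05, unadjusted, under other settings. With normexp correction these were chromosome 4 from 132600001 (-0.22, exact permutation p = 0.0352), chromosome 12 (-0.21, exact permutation p = 0.0484) and chromosome 4 from 21100001 (0.47, exact permutation p = 0.0440). Chromosome 4 from 132600001 also passed without dim probes (-0.30, exact permutation p = 0.0396) and after removal of the probe trend (-0.36, exact permutation p = 0.0286). It passed without F2 3 (-0.33, exact permutation p = 0.0330) or congenic 6 (-0.33, exact permutation p = 0.0302), and chromosome 12 without F1 2 (-0.33, exact permutation p = 0.0440). With the labelled dyes these losses are gains.

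Gains were less recurrent. Distal chromosome 11 from 112700001 to 116900000 was gained in F2 1, F2 3, congenic 3 and congenic 5. The log2 ratio over all mammary tumours was 0.26 ± 0.51 (SD, n = 12). It was 1.81 in F2 3 but 0.40 in F2 1, 0.32 in congenic 3 and 0.39 in congenic 5, so the mean rests largely on F2 3. The non-mammary mean was -0.00 ± 0.05 (SD, n = 3), and the difference of 0.26 did not pass (exact permutation p = 0.279). Chromosome 12 from 114700001 to 115400000 was called gained in 4 mammary and 2 non-mammary tumours, at 0.11 ± 0.20 (SD, n = 12) and 0.26 ± 0.07 (SD, n = 3; exact permutation p = 0.207). These calls depended on the signal used: 0 and 0 tumours kept one with normexp correction, and 1 and 1 without dim probes. Regions of chromosome 1 from 159500001 to 160300000, 172700001 to 176200000 and 186900001 to 191000000 were gained in 3 mammary tumours each, F1 1, F2 3 and congenic 5, and in no non-mammary tumour. F1 1 and F2 3 carried these as part of the whole-chromosome gain, whereas congenic 5 reached 0.98 and 1.03 over segments of 3.53 and 4.11 Mb at the last 2 of them. With the labelled dyes these gains are losses.

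Single tumours also carried high-ratio focal changes, chosen here after their values were seen. F2 3 gained chromosome 14 from 22730309 to 27482064 at a mean log2 ratio of 2.41 and chromosome 9 from 120329247 to 121079551 at 2.32. F2 2 gained chromosome 3 from 89122065 to 94928223 at 1.62 and from 95046558 to 96250757 at 2.26. Congenic 2 lost chromosome 19 from 32408608 to 32994408 at -2.27, and the unnumbered congenic tumour lost chromosome 9 from 96331601 to 96575858 at -1.58. F1 2 lost chromosome 3 from 84417301 to 85310435 at -1.38, and congenic 4 lost chromosome 11 from 5130987 to 5377391 at -1.37. These changes were each picked from 1 array, and they turn from loss to gain or back with the labelled dyes. A shallower loss of F2 3, from 4701913 to 84859219 at -0.42, covers the chromosome 11 loss of congenic 4.

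Mammary tumours of the crosses carried more called segments than those of congenic mice, 41.6 ± 11.9 (SD, n = 5) against 24.6 ± 7.44 (SD, n = 7). F1 tumours averaged 40.5 (n = 2) and F2 tumours 42.3 ± 11.2 (SD, n = 3). The altered share of the autosomes was 10.4% ± 7.24 in crosses and 4.24% ± 5.11 in congenic mice. Segments at the loci left out above, in the comparison with non-mammary tumours, were more frequent in crosses. They numbered 7 in F1 1, 7 in F2 1, 5 in F2 2, 3 in F1 2 and 3 in F2 3. Each congenic mammary tumour had 1. Without such segments, 25 to 48 were left per cross tumour and 13 to 33 per congenic tumour, so part of the difference lay at these loci. With all segments counted, the numbers of segments differed by 17.0 (two-sided exact permutation p = 0.0152, Benjamini-Hochberg value 0.0396). Permuting within slide lot gave an exact permutation p of 0.0286. The difference was 7 in lot A (2 against 5, exact permutation p = 0.429) and 22.7 in lot B (3 against 2, exact permutation p = 0.2, smallest possible 0.1). The altered shares differed by 6.15 percentage points (exact permutation p = 0.115, the same after adjustment), by 8.85 in lot A (exact permutation p = 0.0952) and by -0.904 in lot B (exact permutation p = 1). The altered share passed without F1 2 (8.40, exact permutation p = 0.0394), at a size threshold of 0.35 (8.97, exact permutation p = 0.00379) and with normexp background correction (7.39, exact permutation p = 0.0265). Without F2 3 its difference was smallest, at 3.97 points. The segment counts did not differ for segments of at least 1 Mb (5.31, exact permutation p = 0.149), and no scan day holds mammary tumours of both backgrounds.

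Median ratios over 3 of the 6 recurrent stretches differed between the backgrounds. Each tumour's value is the median over the bins of the stretch, so it follows how far a loss extends as well as its depth. Over the whole chromosome 11 stretch, cross tumours averaged -1.42 ± 0.71 (SD, n = 5) and congenic tumours -0.28 ± 0.23 (SD, n = 7), a difference of -1.14 (exact permutation p = 0.00126, Benjamini-Hochberg value 0.0139 over 11 regions). The inner segment was longer in crosses, 0.380 ± 0.177 Mb (SD, n = 5) against 0.154 ± 0.0658 Mb (SD, n = 7; exact permutation p = 0.0139), whereas its mean log2 ratio differed by -0.47 (exact permutation p = 0.104). Chromosome 4 from 148400001 to 149200000 averaged -0.88 ± 0.73 in crosses (SD, n = 5) and -0.19 ± 0.22 in congenic tumours (SD, n = 7; exact permutation p = 0.00758, Benjamini-Hochberg value 0.0324). At chromosome 4 from 21100001 to 21300000, which every non-mammary tumour had lost too, the order was opposite. Crosses averaged -0.95 ± 1.07 (SD, n = 5) and congenic tumours -2.57 ± 0.17 (SD, n = 7, exact permutation p = 0.00884, Benjamini-Hochberg value 0.0324). With normexp correction the chromosome 11 difference was -0.31 (exact permutation p = 0.00631) and that from 148400001 on chromosome 4 was -0.25 (exact permutation p = 0.053), which did not pass. Without dim probes the difference from 21100001 on chromosome 4 was 0.26 (exact permutation p = 0.134), which did not pass either, and with normexp correction it was 0.50 (exact permutation p = 0.00379). Leaving out dim probes can remove the lost probes themselves, and the normexp offset draws ratios of dim signals towards 0. Both settings can thus shrink a difference between deep losses. Without F1 1, at -2.17 from 148400001 on chromosome 4, that difference fell from -0.69 to -0.37 (exact permutation p = 0.0273, unadjusted). Over the 10 narrower regions named, the chromosome 11 peak differed by -0.98 (exact permutation p = 0.0152), and neither it nor chromosome 4 from 21100001 passed (Benjamini-Hochberg value 0.0758 for both). The losses on chromosome 5 and chromosome 12 and the loss from 132600001 on chromosome 4 differed by -0.10, 0.08 and -0.06, with exact permutation p values of 0.532, 0.605 and 0.662. The comparison of inner segments was added after the values were seen, and signs turn with the labelled dyes.

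The labels give a number of copy-number variants for each tumour, between 30 in uterine congenic 7 and 166 in F2 1. Over all 15 tumours it rose with the number of called segments (Pearson r = 0.594, permutation p = 0.0187; Spearman rho = 0.525, permutation p = 0.0455). Within the 8 congenic tumours r was 0.798 (exact permutation p = 0.0227) and rho 0.778 (exact permutation p = 0.0287). Within the 7 cross tumours r was 0.158 (exact permutation p = 0.711) and rho 0.143 (exact permutation p = 0.783). Leaving out the 2 tumours farthest from the median label number gave r = 0.491, 0.643 and 0.436. Among the 12 relations computed, these 3 had Benjamini-Hochberg values for r of 0.0661, 0.0661 and 0.711. Over all tumours, 11 of 15 alternatives kept direction and side of 0.05 (lowest r 0.429). Within congenic tumours 11 of 15 did (lowest r 0.546), and within cross tumours 15 of 15. The relation that passed was with segments under 100 kb over all tumours (r = 0.627, permutation p = 0.00333, Benjamini-Hochberg value 0.0400; rho = 0.729, permutation p = 0.00248, Benjamini-Hochberg value 0.0298; r = 0.778 without the 2 farthest). It did not pass within the congenic (r = 0.483, exact permutation p = 0.254; rho = 0.626, exact permutation p = 0.107) or the cross tumours (r = 0.289, exact permutation p = 0.498; rho = -0.126, exact permutation p = 0.793). The label numbers differed between cross and congenic mammary tumours by 67.9 (144 against 76.3, exact permutation p = 0.00505) and between mammary and non-mammary tumours by -11.1 (105 against 116, exact permutation p = 0.769). Without uterine congenic 7, r over all tumours was 0.481 (permutation p = 0.0856) and within congenic tumours 0.665 (exact permutation p = 0.0948); without F2 1 the first was 0.518 (permutation p = 0.0562), and without congenic 2 the second was 0.776 (exact permutation p = 0.0583).

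Tests of 24793 bins of 100 kb with limma found 29 bins lost and 22 gained in the 12 mammary tumours against the reference. Lost bins lay on chromosomes 4 and 12 (10 each), 5 (4), 11 (3) and 7 (2). Gained bins lay mainly on chromosomes 1 (15) and X (4). The bin at chromosome 11 from 79200001 to 79300000 averaged -1.34 ± 0.19 (SE, limma adjusted p = 0.0154) and was below 0 in 12 of 12. The bin at chromosome 4 from 133100001 to 133200000 averaged -0.38 ± 0.05 (SE, limma adjusted p = 0.0154), chromosome 5 from 124700001 to 124800000 averaged -0.46 ± 0.07 (SE, limma adjusted p = 0.0182) and chromosome 12 from 81100001 to 81200000 averaged -0.45 ± 0.07 (SE, limma adjusted p = 0.0204). Chromosome X from 154600001 to 154700000 was the bin of smallest adjusted p, at 0.76 ± 0.04 (SE, limma adjusted p = 4.96e-07), and it stood at 0.81 ± 0.05 in the 3 non-mammary tumours (SD). The 15 gained bins of chromosome 1 had small means, such as 0.20 from 41200001 to 41300000. The counts fell to 0 and 0 with trended, robust variances in limma (173 and 56 at unadjusted p under 0.05), to 5 and 3 after removal of a shared probe trend, and to 0 and 1 in cross tumours alone (193 and 376 unadjusted). Congenic tumours alone gave 20 and 19. Normexp correction gave 27 and 5, and means of probes gave 47 and 42. Leaving out any 1 of the 7 congenic tumours left 7 to 18 lost bins, and leaving out F1 1, F2 3 or any numbered congenic tumour left 7 to 14 gained bins.

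Between mammary and non-mammary tumours limma called 0 bins, with 939 at unadjusted p under 0.05. Large differences with a wide spread were thus missed too. The bin at chromosome 11 from 79200001 to 79300000 stood at -1.34 ± 0.74 in mammary (SD, n = 12) and -0.02 ± 0.02 in non-mammary tumours (SD, n = 3). The smallest p values, which did not pass, included chromosome 10 from 78800001 to 78900000 (-0.34 ± 0.06, SE), chromosome 17 from 92700001 to 92800000 (-0.23 ± 0.04) and chromosome 7 from 24400001 to 24500000 (-0.32 ± 0.07), each with an limma adjusted p of 0.952. In the opposite direction they included chromosome 8 from 35400001 to 35500000 (0.24 ± 0.05), chromosome 17 from 62000001 to 62100000 (0.26 ± 0.07) and chromosome 3 from 40200001 to 40300000 (0.18 ± 0.04), also at 0.952. With scan day as a block limma called 346 bins, 324 of them on chromosome 12, which both mammary tumours of day 4 had lost whole. It called 0 on day 4 alone (2269 unadjusted), 0 on days 3 and 4 alone (1456 unadjusted) and 0 with slide lot as a block (1479 unadjusted). Without uterine congenic 7 limma called 4 bins, and without uterine F2 4 it called 2.

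Between cross and congenic mammary tumours limma called 1 bin, with 1607 at unadjusted p under 0.05. That bin, chromosome 6 from 131800001 to 131900000, stood at 0.61 ± 0.06 in crosses (SD, n = 5) and 0.08 ± 0.08 in congenic tumours (SD, n = 7), a difference of 0.52 ± 0.05 (SE, limma adjusted p = 0.00116). The next by p, chromosome 11 from 78600001 to 78700000 (-0.62 ± 0.09, SE, limma adjusted p = 0.191) and chromosome 1 from 90100001 to 90200000 (0.35 ± 0.06, SE, limma adjusted p = 0.201), did not pass. Slide lot as a block gave 1 bin, and scan day as a random block gave 1, the same bin. No scan day holds mammary tumours of both backgrounds, so the latter fit cannot separate background from scan day. Whether this bin follows background or scan day therefore cannot be told. No bin passed limma with normexp correction (1622 unadjusted), without dim probes (1590), after removal of the probe trend (1671) or with trended, robust variances (1579). Averaging probes gave 2 bins, and leaving out F2 1 or F2 2 gave 4 and 15.

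Between the 2 F1 and 3 F2 mammary tumours limma called 0 bins, with 1920 at unadjusted p under 0.05. The smallest p values included chromosome 4 from 149000001 to 149100000, at -2.02 ± 0.21 in F1 (SD, n = 2) and -0.42 ± 0.30 in F2 (SD, n = 3; difference -1.60 ± 0.36, SE, limma adjusted p = 0.638). Chromosome 12 from 80000001 to 80100000 stood at -0.04 ± 0.05 in F1 (SD, n = 2) and -0.64 ± 0.10 in F2 (SD, n = 3; 0.59 ± 0.10, SE, limma adjusted p = 0.638). Chromosome 11 from 69100001 to 69200000 stood at -0.02 ± 0.08 (SD, n = 2) and -0.56 ± 0.10 (SD, n = 3; 0.54 ± 0.10, SE, limma adjusted p = 0.638). Leaving out F1 2 gave 1460 bins, F1 1 gave 193, F2 1 gave 37, F2 3 gave 4 and F2 2 gave 1; a lone F1 tumour was then assumed to vary like the other groups.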

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

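Tests chosen only after the result was seen were the Cy3 share in processed signals, the strain probes, the segments of at least 1 Mb, and all tests of the chromosome 11 loss; raw signals and the random splits were chosen earlier. Ratios are log2 of Cy3 over Cy5.

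A gap test for single samples was run in 24 groups of 4 to 10 tumours and made 6 marks, in 4 tumours; chance marks about 1 in 20 groups. Cross mammary tumours were pooled over F1 and F2 for it. Congenic 5 had 20 called segments of at least 1 Mb, far above the other congenic mammary tumours. F1 2 had the label number 89, far below the other cross mammary tumours. F2 2 stood apart 3 times. It had -2.77 at chromosome 4 from 21100001 to 21300000, within the -3.02 to -2.31 of the congenic tumours, and -0.32 on chromosome X. Its Cy3 signal was 0.48 at probes whose Cy5 signal differs between scan days. F2 3 stood apart with 1.81 at the distal chromosome 11 gain.

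Cross and congenic mammary tumours differed by exact permutation tests at 3 recurrent losses. The differences were 1.62 at chromosome 4 from 21100001, -0.69 at chromosome 4 from 148400001 and -1.14 at chromosome 11 from 78600001 (exact permutation p = 0.00884, 0.00758 and 0.00126). Background and scan day cannot be told apart here.

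Chromosome Y probes entered no comparison, and their Cy5 signal was higher by 0.62 on scan days 1 and 2 than on days 3 and 4 (5 against 10 arrays, exact permutation p = 0.000333, the smallest possible). The Cy5 signal of chromosome X differed by -0.15 with the same p. The Cy3 signal of chromosome Y differed too, by -0.35 (exact permutation p = 0.000333). That of chromosome X differed by -0.11 (exact permutation p = 0.0526) through F2 2 (-0.52), whose X was lost. The other 4 arrays of days 1 and 2 stood at -0.08 to -0.03, within the -0.12 to 0.03 of days 3 and 4. Whether the DNA in Cy5 or another property of the scan days differed was not tested.

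The change in the ratios lay in the Cy3 channel, which the labels give to the reference. Dye normalization by the scanner software is argued against, since the median Cy3 share was 1.02 (1.018) in raw signals and 1.01 (1.008) in processed signals. At 2296 probes chosen on Cy5 alone, the 2 F2 tumours of scan day 4 exceeded the 3 congenic ones by 1.002 in Cy3 and by -0.01 in Cy5. That mean rests on 2 unlike values, 0.55 in uterine F2 4 and 1.45 in bone F2 5, and F2 4 alone would miss the criterion of 1 set for it. The shares and these signals are consistent with tumour DNA in Cy3. A mistake in the labels and one in the channels of the files stay open, as untested.

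Uterine F2 4 and bone F2 5 had label numbers of 158 and 159 but few large changes. Somatic changes of at least 1 Mb are argued against: the higher of the 2 had 3 such segments, against a median of 6.5 in mammary tumours. The lower median ratio at the strain probes was 0.796 (0.7958), above the 0.05 to 0.25 of the 8 congenic tumours but short of the criterion of 1 or more in both. Its rank above the 5 cross mammary tumours says nothing, because the probes were chosen on a higher Cy5 signal in those, which lowers their ratios. Whether strain variants add to these label numbers stays open, and how the labels counted is not known here.

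The chromosome 11 loss was seen in mammary tumours alone. A probe trend shared by arrays is argued against, since 11 mammary tumours kept a call at the peak after its removal. A strain variant is argued against by the non-mammary tumours of both backgrounds, whose lowest ratio was -0.03 (-0.0318), and scan day by the 2 mammary tumours of day 4, which averaged -0.80 (-0.8008). The tissue of the tumour may explain the difference (exact permutation p = 0.011), but the region was chosen on mammary calls, and this p did not pass adjustment over 10 regions. Tumour content, which was not measured, stays open.

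For mammary against non-mammary, the real count was 0, so each of the 100 splits drawn gave as many by construction (100 of 100) and the splits say nothing about chance; the highest other split gave 12. For cross against congenic, 3 of 100 splits gave as many as the real count of 1, a share under 0.05, but the highest other split gave 3. The bin did not pass with normexp correction, without dim probes, after removal of the probe trend or with trended, robust variances (0 bins in each), so chance is not firmly excluded.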

How the results depend on the processing

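Labelled dyes, probe trend, scan day, single slide lots for the crosses, cross tumours only, strain loci, the halved penalty, the numbered tumours without a block and single tumours left out for whole stretches were tried only after the results were seen. Of 209 alternatives of 14 results, leaving single tumours out aside, 166 kept direction and side of the threshold, as did 150 of 183 that left out 1 tumour and 53 of 66 for the region means. The cause was not tested except where the construction shows it.

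With the labelled dyes all signs turn by construction: recurrent lost bins were 0 and gained bins 51. The mammary means of the losses became 1.89, 0.33, 0.48, 0.35, 0.76 and 0.32 (chromosome 4 from 21100001, 132600001 and 148400001, chromosomes 5, 11 and 12). Those of the gains became -0.26 (chromosome 11), -0.11 (chromosome 12) and -0.18, -0.18 and -0.13 (chromosome 1 from 186900001, 159500001 and 172700001).

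With normexp, the altered genome of cross against congenic differed by 7.39 and the label number of congenic tumours had r = 0.546. Gained bins were 5 and cross against congenic bins 0. With probes well above background alone, r was 0.485 over all and 0.720 in congenic tumours, and cross against congenic bins were 0. Chromosome 4 from 21100001 moved to -0.67 and -0.56 under these settings, the second of which can remove the lost probes themselves. Normexp also moved chromosome 11 from 78600001 from -0.76 to -0.35 and chromosome 4 from 148400001 from -0.48 to -0.26.

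A size threshold of 0.15 gave r = 0.691 in congenic tumours and 12 recurrent gained bins; 0.35 gave a mammary difference of 17.8 segments and a cross difference of 8.97 points. A minimum of 20 probes gave r = 0.480 over all, the doubled penalty 0.670 in congenic tumours, segments of at least 100 kb 0.485 over all, and strain loci left out 0.429 over all. Segments of at least 1 Mb gave differences of 6.5 (mammary) and 5.31 (cross) and 19 recurrent lost bins; no minimum length gave 1 recurrent gained bin.

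Slide lot B alone, with fewer tumours, gave a mammary difference of 27.9 segments and 10.6 points of altered genome, and a cross difference of 22.7 segments and -0.904 points, the latter reversed. Lot A alone gave a cross difference of 7 segments, and scan day 4 alone a mammary difference of 14.3.

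In limma, bins lost and gained against the reference and bins of cross against congenic were 47, 42 and 2 with means of probes, 5, 3 and 0 after removal of the probe trend, and 0, 0 and 0 with trended, robust variances. No minimum size gave 109 lost and 172 gained bins, cross tumours only gave 0 and 1, and congenic tumours only 20 and 19. Scan day as a block gave 346 bins for mammary against non-mammary.

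A replicate block on numbers 1 to 3 gave 0 bins for cross against congenic (855 at unadjusted limma p under 0.05), and the same 8 tumours without it gave 0 (880), so the paired fit changed no call there. Numbers 1 and 2 each have an F1 and an F2 tumour, and each congenic tumour was set against the mean of the cross tumours of its number. These correlated at 0.0493, 0.0137 and -0.0064; tumours numbered 1 and 2 correlated best with their own number, those numbered 3 did not, and the numbers were not taken to pair the tumours.

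Leaving out 1 tumour gave, for mammary against non-mammary, 15.2 to 24.2 segments, 5.48 to 7.18 points and 0 to 4 bins. For cross against congenic it gave 13.7 to 20.4 segments, 3.97 to 8.40 points and 1 to 15 bins. The r of the label number was 0.481 to 0.743 over all, 0.665 to 0.885 in congenic and -0.0833 to 0.334 in cross tumours, reversed without F2 1 (-0.0131) and F1 2 (-0.0833). Recurrent lost bins were 41 to 51 and gained 0; bins against the reference were 7 to 31 lost and 7 to 25 gained; F1 against F2 gave 0 to 1460.

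A GC correction, the camera test and the gene-list test were not run, since genes and sequences could not be placed on the array's build.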

Other observations

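All observations in this part were chosen after the values were seen. A second focal loss lay on chromosome 11, where the bins from 69200001 to 69400000 were lost in 5 of the 12 mammary tumours and gained in 0. Its inner segments stood at -1.78 in F2 1 (69328907 to 69449632), -2.05 in F2 2 (69356941 to 69422912) and -1.42 in F2 3 (69253324 to 69414063). They stood at -0.85 in congenic 6 (69369174 to 69445696) and -0.61 in congenic 5 (69181304 to 69563203). Ratios are log2 of Cy3 over Cy5 and turn sign with the labelled dyes.

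Distal chromosome 11 of congenic 5 was gained in steps, from 0.89 (115473005 to 115996696) over 0.28 (115997980 to 116353294) to 1.64 (116354721 to 118171449), 0.82 (118173717 to 118405177) and 0.33 (118406158 to 119911558). It rose again to 1.61 (119913195 to 120257042), fell to 0.47 (120258851 to 120695271), reached 1.84 (120696294 to 120979009) and ended in a loss at -0.41 (120980515 to 121809961). F2 3 was gained at 1.18 from 99130282 to 110286995 and at 2.61 from 110288310 to 110749319. Distal chromosome 1 of congenic 5 alternated as well, with gains of 0.98 (172679889 to 176214281), 1.44 (179027174 to 179673900) and 1.03 (186936252 to 191043095), and a loss of -0.35 from 191044659 to 197158988. No explanation was tested.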
